A study of Mus musculus with 16 samples.

How the data were processed

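Bulk RNA-seq libraries of striatum were compared, 16 in all and 4 in each of 4 groups, each taken as 1 mouse. For libraries that held both female and male transcripts, described below, 1 mouse per library is uncertain. Mice were wild type or carried a knockout of Sapap3, whose current symbol is Dlgap3, the gene of a scaffold protein of corticostriatal postsynaptic densities. An adeno-associated virus delivered to the striatum made astrocytes express either the fluorescent protein tdTomato or hM4Di, an engineered Gi-coupled receptor derived from the human muscarinic M4 receptor. All mice received deschloroclozapine, the agonist of hM4Di, per the labels' protocols. The groups are called WT_tdT, WT_hM4D, KO_tdT and KO_hM4D below, with a replicate number per mouse as the labels give it. For 3 wild-type hM4Di libraries 1 label field named another group, and the group was taken from the title and the genotype field.

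RNA was purified with a column kit and made into stranded total RNA libraries after removal of ribosomal RNA, per the labels' protocols. The authors deposited 1 table of raw read counts, as whole numbers per gene and library, for 48795 genes. Read files were made with bcl2fastq 2.17, reads were aligned with STAR and counted with HTSeq, and the builds named are GRCm38 and mm10, per the submitters' processing notes. The versions of STAR and HTSeq, the annotation release, the strand setting of the counting and any filter are not given in the sources used here. Without the strand setting, overlapping genes on opposite strands are uncertain, and so are genes that share reads with near-identical copies. The table held 0 entries that name no gene. Of its gene identifiers 48435 were matched to GENCODE M21 on GRCm38, which supplied coordinates and gene types, and 48421 of these had the same chromosome and strand. Among the identifiers 260 share a symbol with another.

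Library totals ranged from 129149745 to 180655067 counts. The mitochondrial genome gave 10.0 to 12.3% of counts per library, the gene with the most counts took 6.57 to 7.83%, and 26451 to 28032 genes had at least 1 count. In all 24 within-group pairs of libraries the counts differed by more than sampling noise (chi-square per degree of freedom of 13.4 to 151), so each library counted as 1 replicate. At this depth the median standard error of a log2 change was 0.08 in a comparison of 2 groups, 0.11 in the interaction and 0.06 in the averaged comparisons. The spread between libraries, rather than counting error, sets that precision.

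The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which left 20825, libraries were scaled with TMM factors, and 1 quasi-likelihood model with a coefficient per group was fitted to all 16 libraries (12 residual degrees of freedom, common dispersion 0.0162, biological coefficient of variation 0.127). Quasi-likelihood F tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested, and a gene was called at an adjusted p under 0.05. All adjusted p of single genes are from this edgeR test unless another tool is named. The 7 comparisons were both genotype comparisons within a virus, both virus comparisons within a genotype, their interaction, and the averages of the genotype and of the virus comparisons. Levels are CPM (counts scaled to library size) with TMM factors, as mean ± SD over 4 libraries. Log2 changes are given with their standard error (SE).

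Gene lists for 27 cell types, pathways and tissue states were tested in each comparison with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and the 189 p-values were adjusted together. Of these tests 83 passed, and 4 also passed with an estimated correlation: the immediate early genes in KO_tdT against WT_tdT and in WT_hM4D against WT_tdT, and the reactive astrocyte genes in WT_hM4D against WT_tdT and in hM4Di against tdTomato over both genotypes. Estimated correlations were often far above the preset one (0.893 for the striatal projection neuron markers in KO_tdT against WT_tdT), so the adjusted p with an estimated correlation stands beside each list that passed. List members called were counted over all genes and also adjusted over the list alone. A few genes stand in 2 lists, among them Calb2, Arl4d, Hspb1, Fkbp5, Cxcl10 and Nlgn1.

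The groups, comparisons, tests, gene lists, thresholds and alternatives were fixed before the data were examined, except the alternatives named as later additions in the closing section. Genes were named by this rule. Dlgap3 and Chrm4 were named in the 4 pairwise comparisons and the interaction. Of the called genes with a mean of at least 1 CPM in a group compared, the 10 largest changes in each direction were named (5 in the interaction and in the averaged comparisons), and so were up to 10 called members of the lists. Where fewer than 5 genes were called, the 5 of smallest p are given as values. Gene models without a descriptive symbol were counted and named only where fewer than 10 others qualified, and each list is described by its 2 to 4 members of smallest p.

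Replicate numbers recur in each group, but the labels do not say that a number marks a shared litter, day or batch. Deviations from the group means of same-numbered libraries had correlations across genes of -0.38 to 0.56 with a median of 0.03 over 24 pairs. In KO_hM4D against WT_hM4D all 4 same-numbered pairs were above 0.1 (0.56, 0.49, 0.30 and 0.24), so a fit of these libraries with the number as a block is printed beside that comparison. That pairing comes from the values alone.

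Comparisons that share a group share its chance values. For these, unchanged groups were simulated against the same libraries 20 times and the shared group was split 2 and 2 in all 6 ways. The tests were tried on simulated counts before use. In a simulated KO_tdT against WT_tdT with 20802 genes in the fit, edgeR recovered 50.8% of genes changed 1.5-fold, 65.2% of those changed 2-fold and 97.0% of those changed 4-fold, and 7 of its 148 calls were unchanged genes. The simulated comparisons without changed genes, WT_hM4D against WT_tdT and KO_hM4D against WT_hM4D, gave 0 calls. On a simulated KO_tdT against WT_tdT with 20795 genes, camera gave a list of 30 genes shifted by 0.5 on the log2 scale a p of 6.34e-73, and 1 of 20 random lists had a p under 0.05. In this trial, and in the fit of KO_hM4D and WT_hM4D with a block, camera was given the counts with their dispersions, not log2 CPM. Counts in these trials of edgeR and camera were drawn independently for each gene. They therefore do not test the preset correlation, or the rate of false calls, where genes vary together as in the real libraries. In a simulated full reversal over 20825 genes, all 192 changed genes that were called had the opposite sign in the other comparison. Unchanged groups that shared the KO_tdT libraries already gave 96.4% opposite signs, so this trial does not show that signs can detect a reversal.

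Alternatives were other scalings (DESeq2 size factors and library totals), no filter and a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, fits of only the groups compared, a replicate block, thresholds of 0.1 and of a 2-fold change, a term for sex, and leaving out each library in turn. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Reads and viral transcripts were not analysed here.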

Results

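Striatal gene expression was measured by sequencing ribosome-depleted RNA in 16 libraries, 4 in each combination of genotype and virus, each library taken to stand for a mouse. Wild-type mice and Dlgap3 (Sapap3) knockout mice, a model of compulsive grooming, carried either tdTomato (the groups WT_tdT and KO_tdT) or the inhibitory designer receptor hM4Di (WT_hM4D and KO_hM4D) in striatal astrocytes. All received the receptor's agonist. The series concerns astrocyte morphology in this model, and the design asks what the knockout changes in the striatum, and what activating a Gi-coupled receptor in astrocytes changes in each genotype. Libraries held 131828601 to 180655067 counts in WT_tdT, 136604299 to 174325860 in WT_hM4D, 129149745 to 146505568 in KO_tdT and 142260564 to 175318609 in KO_hM4D. No group received hM4Di without agonist, so effects of the receptor, of its activation and of the vector's payload are measured together.

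Dlgap3, which encodes a postsynaptic scaffold protein enriched at corticostriatal synapses (ENSMUSG00000042388, GRCm38 chromosome 4, 127169204 to 127237022), separated the genotypes in every library. Its level was 375.2 ± 60.65 CPM in WT_tdT and 391.6 ± 37.4 CPM in WT_hM4D (SD, n = 4). It was 159.9 ± 3.595 CPM in KO_tdT and 159.5 ± 7.47 CPM in KO_hM4D. The lowest wild-type library, WT_tdT 2, stood at 294.4 CPM and the highest knockout library at 166.6 CPM, so 8 of 8 knockout libraries lay below 8 of 8 wild-type libraries. The knockout therefore still gave reads counted to the gene. Dlgap3 did not differ between viruses, with a log2 change of -0.00 (SE 0.09, edgeR adjusted p = 0.991) in knockouts and 0.06 (SE 0.09, edgeR adjusted p = 0.858) in wild types.

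**Figure D1:**
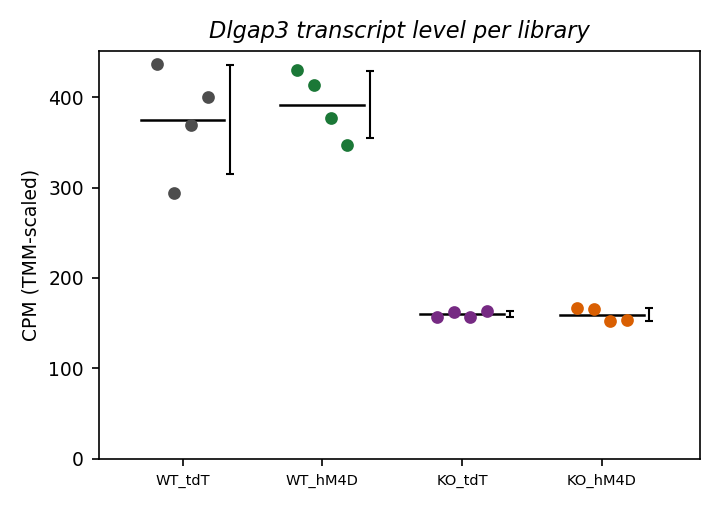
Dlgap3 in each library, in TMM-scaled CPM on the y axis for the 4 groups on the x axis, with a line at each group mean and bars of 1 SD (n = 4). All knockout libraries lie at or below 166.6 CPM and all wild-type libraries at or above 294.4 CPM.

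Chrm4, the mouse gene of the muscarinic receptor from whose human counterpart hM4Di was made (GRCm38 chromosome 2, 91927249 to 91928688), was counted at 57.15 ± 7.001 CPM in WT_tdT and 85.96 ± 5.20 CPM in WT_hM4D (SD, n = 4). It was 54.1 ± 15.3 CPM in KO_tdT and 76.34 ± 10.2 CPM in KO_hM4D. The log2 change with hM4Di was 0.59 (SE 0.15, edgeR adjusted p = 0.155) in wild types and 0.50 (SE 0.15, edgeR adjusted p = 0.287) in knockouts, and neither passed the test over all genes. In wild types all 4 hM4Di libraries lay above all 4 tdTomato libraries, and DESeq2 gave an adjusted p of 0.0187, within a range of 0.0187 to 0.391 over the alternatives. Reads of the viral receptor that resemble Chrm4 cannot be told from mouse transcripts in these counts. The log2 difference in Chrm4 between genotypes was -0.08 (SE 0.15, edgeR adjusted p = 0.920) with tdTomato and -0.17 (SE 0.15, edgeR adjusted p = 0.640) with hM4Di.

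The first comparison, KO_tdT against WT_tdT, measured the knockout under the control virus. Activity-induced genes were lower in knockouts. Fos, a subunit of the AP-1 transcription factor, was 39.96 ± 11.2 CPM in WT_tdT and 13.73 ± 4.79 CPM in KO_tdT (SD, n = 4), a log2 change of -1.54 (SE 0.25, edgeR adjusted p = 0.0279). Btg2, an antiproliferative early gene (GRCm38 chromosome 1, 134075170 to 134079120), fell from 21.31 ± 5.75 to 8.41 ± 0.454 CPM, a log2 change of -1.34 (SE 0.16, edgeR adjusted p = 0.00393). Dusp1, a phosphatase of MAP kinases (GRCm38 chromosome 17, 26505590 to 26562128), changed by -0.94 (SE 0.13, edgeR adjusted p = 0.0132), and Cyr61, a secreted matricellular protein, by -1.19 (SE 0.18, edgeR adjusted p = 0.0205). Csrnp1, a serum-responsive nuclear gene, changed by -0.63 (SE 0.09, edgeR adjusted p = 0.0132). For these 5 genes every knockout library lay below every wild-type library.

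Among the 30 immediate early genes measured, 4 fell and 0 rose over all genes, 16 fell adjusted over the list alone, and 24 had a negative change, with a median log2 change of -0.50 (camera adjusted p = 8.72e-32, adjusted p = 0.0264 with an estimated correlation). Junb (-1.09, SE 0.20) and Gadd45b (-0.48, SE 0.09) were among those passing over the list alone. Clock genes moved both ways. Of 19 measured, 3 were lower adjusted over the list alone, the repressor Nr1d1 (-0.57, SE 0.12), Ciart (-0.74, SE 0.16) and Usp2 (-0.30, SE 0.06), and 2 were higher, Cry1 (0.30, SE 0.10) and Per2 (0.42, SE 0.15), with a camera adjusted p of 0.0876 for the list. Heat shock and chaperone genes were higher, 15 of 15 in sign and 7 adjusted over the list alone, with a median log2 change of 0.18 (camera adjusted p = 9.09e-10, adjusted p = 0.420 with an estimated correlation). They included the endoplasmic reticulum chaperone Hspa5 (0.58, SE 0.14) and the inducible Hspa1b (1.28, SE 0.34).

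Markers of neurons outside the striatum also differed in this comparison. Of 20 thalamic, septal and pallidal neuron markers 19 had a positive change, 0 passed over all genes and 6 passed adjusted over the list alone, with a median log2 change of 0.85 (camera adjusted p = 7.58e-11, adjusted p = 0.420 with an estimated correlation). Calb2, a calcium-binding protein that is also a striatal interneuron marker, changed by 1.33 (SE 0.30), and the transcription factor Shox2 by 6.72 (SE 1.89). The mean log2 level of this list was 1.97, 2.43, 3.88 and 3.05 in KO_tdT 1 to 4 and 1.90 on average in WT_tdT. Markers of striatal projection neurons were lower in 20 of 21 cases with a median of -0.20 (camera adjusted p = 0.000244, adjusted p = 0.662 with an estimated correlation), and 0 passed adjusted over the list alone. Their mean log2 level was 8.18 to 8.27 in KO_tdT 1 to 3, but KO_tdT 4, at 8.941, lay above all of WT_tdT (8.21 to 8.931). Astrocyte markers were slightly higher (19 of 24 positive, median 0.07, camera adjusted p = 0.00118, adjusted p = 0.498 with an estimated correlation), and 1 passed adjusted over the list alone, the growth factor receptor Fgfr3 (0.26, SE 0.07). Oligodendrocyte markers (16 of 18 negative, median -0.13, camera adjusted p = 0.0423, adjusted p = 0.772 with an estimated correlation) and endothelial and mural markers (17 of 23 negative, median -0.06, camera adjusted p = 0.0153, adjusted p = 0.498 with an estimated correlation) were lower.

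No difference was detected in the lists closest to the series' question. The 45 genes of astrocyte morphology and actin regulation (camera adjusted p = 0.575), 40 of Gi signalling and cAMP (0.751), 18 synaptogenic and matricellular astrocyte genes (0.0870), 26 reactive astrocyte genes (0.263) and 39 postsynaptic density genes (0.691) had 0 members passing adjusted over the list alone. The other lists had camera adjusted p between 0.0736 and 0.994 here. Of those, 1 interneuron marker (Calb2) and 2 glucocorticoid response genes passed adjusted over the list alone. The last were Arl4d (-0.72, SE 0.17) and the stress-induced Ddit4 (-0.44, SE 0.13).

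In total 8 genes were lower and 0 higher of 20825 tested with edgeR in KO_tdT against WT_tdT, 1810 had an unadjusted p under 0.05, and DESeq2 called 15 higher and 49 lower. Besides Dlgap3 (-1.23, SE 0.10, edgeR adjusted p = 1.41e-05), Fos, Btg2, Dusp1, Cyr61 and Csrnp1, the last outside the list of immediate early genes, the calls were Dcdc2b and CK137956. Both were under 1 CPM, on chromosome 4 near Dlgap3 and named after their values were seen. The count was 2 without KO_tdT 2, KO_tdT 3 or WT_tdT 3, 3 without WT_tdT 4, 32 without KO_tdT 4, and 1 with only the libraries of these groups in the fit. Fos lost its call without any of 9 single libraries, Cyr61 without 6, Dusp1 without 4 and Csrnp1 without 3, while Btg2 and Dlgap3 kept theirs in the 23 alternatives with all groups in the fit. With only the libraries of these groups Dlgap3 was the gene still called (-1.23, SE 0.11, edgeR adjusted p = 0.0149) and Btg2 was not (edgeR adjusted p = 0.152), and with a replicate block in that fit Dlgap3 was not called either (-1.22, SE 0.10, edgeR adjusted p = 0.360). Without the 4 libraries that hold both Xist and Y-linked transcripts at 5% or more, Dlgap3 was the 1 call and Btg2 was not called (edgeR adjusted p = 0.135), and with KO_tdT 4 left out as well the count was 62. Of these groups the fit with 62 calls held only KO_tdT 1 and 2 and WT_tdT 1, 2 and 3.

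**Figure D2:**
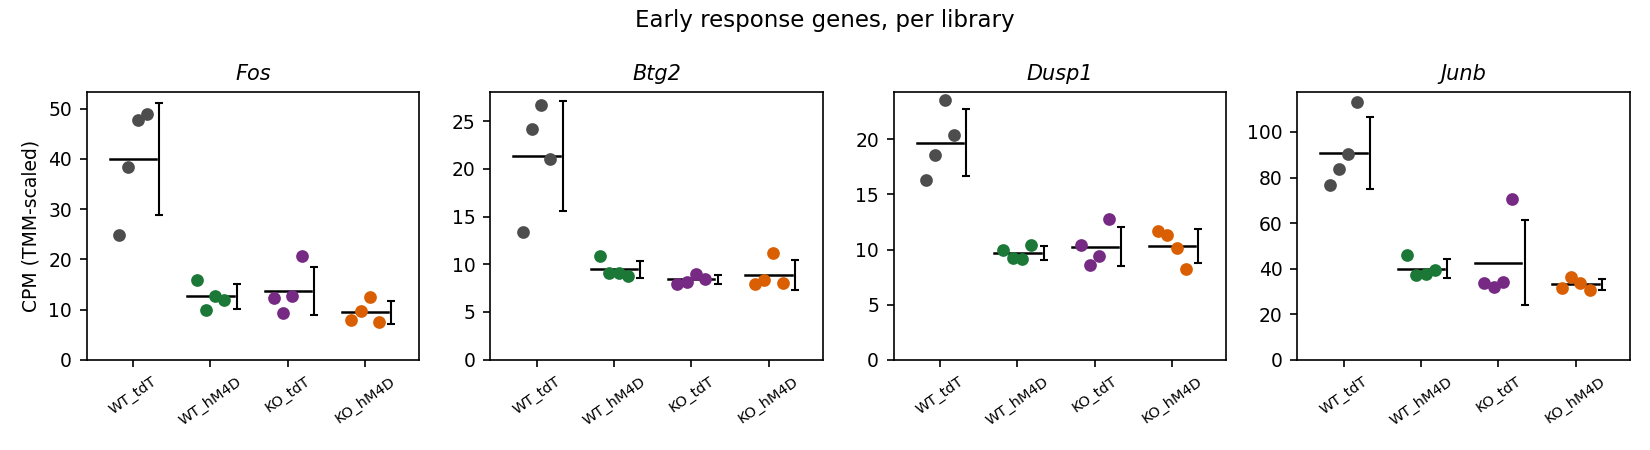
Immediate early genes Fos, Btg2, Dusp1 and Junb in each library, in TMM-scaled CPM on the y axes for the 4 groups on the x axes, with a line at each group mean and bars of 1 SD (n = 4). WT_tdT stands above the other groups for all 4 genes, for example for Dusp1 at 19.7 ± 3.06 CPM against 9.69 ± 0.601 CPM in WT_hM4D, 10.27 ± 1.80 CPM in KO_tdT and 10.36 ± 1.55 CPM in KO_hM4D.

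The comparison of WT_hM4D with WT_tdT measured the activated receptor in wild-type astrocytes. Genes of reactive astrocytes were higher. C4b, a complement component (GRCm38 chromosome 17, 34728380 to 34743882), rose from 22.63 ± 4.94 to 84.22 ± 11.2 CPM (SD, n = 4), a log2 change of 1.90 (SE 0.21, edgeR adjusted p = 0.000767). Serpina3n, a secreted protease inhibitor (GRCm38 chromosome 12, 104406729 to 104414329), rose from 6.29 ± 0.760 to 17.87 ± 3.09 CPM, a log2 change of 1.51 (SE 0.16, edgeR adjusted p = 0.000602). The intermediate filament genes Gfap (GRCm38 chromosome 11, 102887336 to 102900912) and Vim (GRCm38 chromosome 2, 13573927 to 13582826) rose by 1.33 (SE 0.15, edgeR adjusted p = 0.00107) and 0.90 (SE 0.09, edgeR adjusted p = 0.000602). For these 4 genes all 4 hM4Di libraries lay above all 4 controls.

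Of the 26 reactive astrocyte genes 4 rose over all genes and 0 fell, 11 rose adjusted over the list alone, and the median log2 change was 0.31 (camera adjusted p = 2.13e-21, adjusted p = 0.0205 with an estimated correlation). The fourth was Timp1, an inhibitor of matrix metalloproteinases (2.50, SE 0.37, edgeR adjusted p = 0.0107), below 1 CPM in both groups. General astrocyte markers did not pass (camera adjusted p = 0.214, 0 of 24 adjusted over the list alone), nor did Gi signalling and cAMP genes (0.469), morphology and actin genes (0.975) or synaptogenic genes (0.783).

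**Figure D3:**
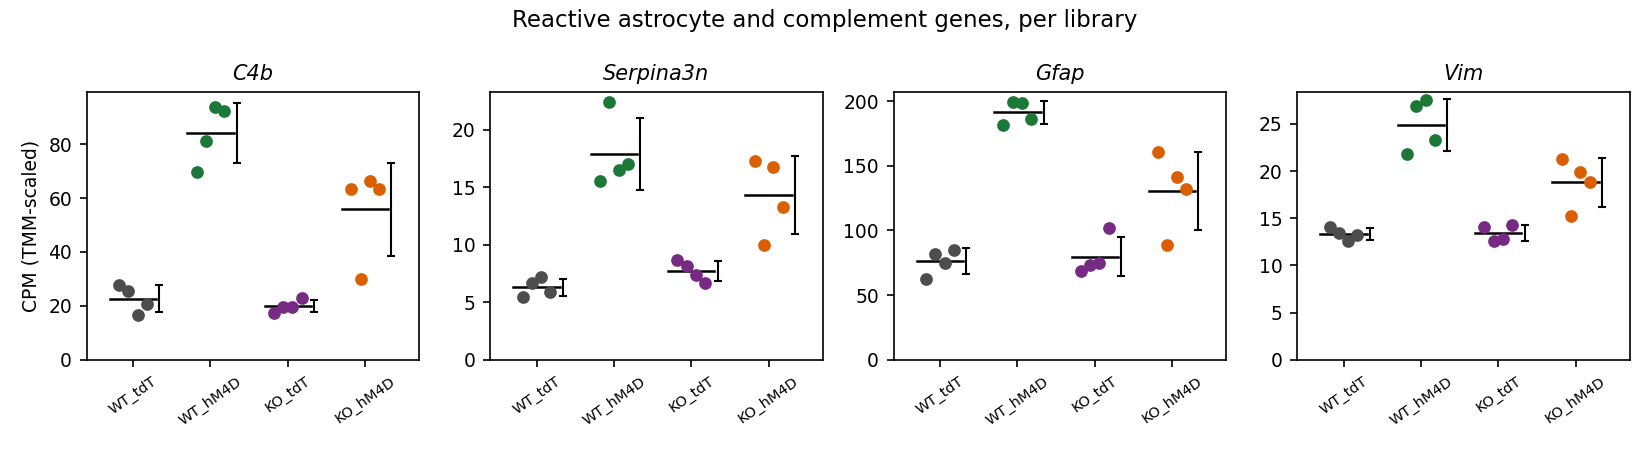
C4b, Serpina3n, Gfap and Vim in each library, in TMM-scaled CPM on the y axes for the 4 groups on the x axes, with a line at each group mean and bars of 1 SD (n = 4). Both hM4Di groups stand above the tdTomato groups, C4b at 84.22 ± 11.2 CPM in WT_hM4D and 55.78 ± 17.3 CPM in KO_hM4D, where replicate 2 lies lowest at 29.93 CPM.

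Immune genes were higher as well. Oasl2, an interferon-induced gene of the oligoadenylate synthetase family, rose from 1.14 ± 0.135 to 3.01 ± 1.19 CPM (log2 change 1.40, SE 0.22, edgeR adjusted p = 0.0213). Of 36 interferon response genes 36 had a positive change, 1 rose over all genes and 17 rose adjusted over the list alone, among them Ifit3 (0.62, SE 0.12) and Bst2 (0.95, SE 0.19), with a median of 0.49 (camera adjusted p = 4.80e-23, adjusted p = 0.158 with an estimated correlation). Of 23 antigen presentation genes 13 rose adjusted over the list alone, among them the immunoproteasome subunit Psmb8 (0.52, SE 0.15) and the class II gene H2-Eb1 (1.53, SE 0.45), with a median of 0.51 (camera adjusted p = 7.45e-11, adjusted p = 0.420 with an estimated correlation). The mean log2 level of this list was 2.73 and 2.19 in WT_hM4D 3 and 4, while WT_hM4D 1 and 2, at 1.53 and 1.71, lay within the 1.39 to 1.73 of WT_tdT. Microglia markers were higher in 19 of 20 cases and 6 passed adjusted over the list alone, such as Ctss (0.37, SE 0.08) and Tmem119 (0.39, SE 0.10), with a median of 0.17 (camera adjusted p = 3.75e-09, adjusted p = 0.426 with an estimated correlation). Of 14 lymphocyte markers 3 passed adjusted over the list alone, the immunoglobulin light chain Igkc (5.97, SE 1.5029), Ptprc (0.40, SE 0.10) and Cxcr6 (3.69, SE 1.0009), with a camera adjusted p of 0.449 for the list. Fam167a (0.83, SE 0.14) and the glycosyltransferase Galnt7 (0.34, SE 0.06) also rose, with an edgeR adjusted p of 0.0315 each.

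Immediate early genes were lower in WT_hM4D than in WT_tdT. Fos fell to 12.64 ± 2.45 CPM, a log2 change of -1.66 (SE 0.25, edgeR adjusted p = 0.0107). Cyr61 (-1.22, SE 0.18, edgeR adjusted p = 0.0107), Junb (-1.18, SE 0.20, edgeR adjusted p = 0.0315), Btg2 (-1.17, SE 0.16, edgeR adjusted p = 0.00689) and Dusp1 (-1.02, SE 0.13, edgeR adjusted p = 0.00335) fell too. So did Apold1 (-1.05, SE 0.17, edgeR adjusted p = 0.0270) and the growth arrest gene Gadd45b (-0.60, SE 0.09, edgeR adjusted p = 0.0159). Of the 30 in the list 6 fell over all genes, 20 fell adjusted over the list alone and 0 rose, with a median of -0.53 (camera adjusted p = 1.70e-33, adjusted p = 0.0264 with an estimated correlation). This comparison and that of KO_tdT with WT_tdT share the WT_tdT libraries, and 4 genes, Fos, Btg2, Dusp1 and Cyr61, were lower in both. Independent lists of these sizes share 0.00307 genes, unchanged groups set against the same controls shared 0, and with WT_tdT split 2 and 2 the mean over 6 ways was 0.333 genes. The first value leaves out the shared controls. Simulated comparisons without changed genes gave 0 calls in a trial, so a shared count of 0 carries little weight. Neither value tells the overlap from an effect of the shared controls. Across 20825 genes, which are not independent replicates, the changes of both comparisons had r = 0.45 and a covariance of 0.0396. Unchanged groups gave r = 0.49 and a covariance of 0.0256, and the split controls gave r = 0.14 and a covariance of 0.0204.

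Further lists passed here only with the preset correlation. Heat shock genes were higher (12 of 15, median 0.11, camera adjusted p = 0.000193, adjusted p = 0.505 with an estimated correlation), with Hspb1 (0.92, SE 0.20) and Hspa5 (0.59, SE 0.14) among 3 passing adjusted over the list alone. Cholesterol synthesis genes (21 of 25 negative, median -0.08, camera adjusted p = 0.000846, adjusted p = 0.622 with an estimated correlation) and mitochondrially encoded genes (13 of 13 negative, median -0.21, camera adjusted p = 0.00416, adjusted p = 0.662 with an estimated correlation) were lower. The mitochondrial list had mean log2 levels of 7.45, 7.14, 6.97 and 6.90 in WT_hM4D 1 to 4 against 7.22 to 7.38 in WT_tdT, so WT_hM4D 1 lay above every control. Ependymal and choroid plexus markers were higher (median 0.25, camera adjusted p = 0.00198, adjusted p = 0.498 with an estimated correlation), as were oligodendrocyte precursor markers (median 0.13, camera adjusted p = 0.00416, adjusted p = 0.505 with an estimated correlation). The ependymal list had mean log2 levels of -0.005, -0.225, 0.037 and 0.524 in WT_hM4D 1 to 4. WT_hM4D 2 thus lay within the -0.444 to -0.115 of WT_tdT. Thalamic, septal and pallidal markers were higher (median 0.46, camera adjusted p = 0.00308, adjusted p = 0.662 with an estimated correlation) and cortical excitatory neuron markers lower (median -0.17, camera adjusted p = 0.0207, adjusted p = 0.714 with an estimated correlation). Postsynaptic density genes were lower (median -0.05, camera adjusted p = 0.0133, adjusted p = 0.505 with an estimated correlation). The other lists had camera adjusted p between 0.0806 and 0.975. Of 18 glucocorticoid response genes 2 were higher and 7 lower adjusted over the list alone, led by Arl4d (-0.80, SE 0.17) and Plin4 (2.02, SE 0.54). Of 19 clock genes 2 were higher (Cry1 0.51, SE 0.10, and Per2 0.67, SE 0.15) and 3 lower (Nr1d1 -0.63, SE 0.12, Ciart -0.76, SE 0.16, and Usp2), and of the endothelial markers Cldn5 (0.34, SE 0.08) was higher.

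In total 10 genes rose and 8 fell of 20825 in WT_hM4D against WT_tdT with edgeR, 2302 had an unadjusted p under 0.05, and DESeq2 called 158 higher and 82 lower. The count ranged from 6 without WT_tdT 4 to 65 without KO_tdT 2, and it was 9 without WT_hM4D 3, 8 without WT_tdT 3, 28 without KO_tdT 3, 38 without KO_tdT 4, 42 without WT_hM4D 2, 49 with only these groups in the fit and 113 with a term for striatal minus cortical markers. In the 23 alternatives with all groups in the fit Gfap, Serpina3n and Vim kept their calls, and C4b, Btg2 and Dusp1 lost theirs only without the 5 libraries that hold both Xist and Y-linked transcripts. With only these groups in the fit all 6 were called, and with a replicate block added Btg2 was not (edgeR adjusted p = 0.187). Other calls were less stable. Of the 23 alternatives Junb was lost in 10, Galnt7 and Fam167a in 9 each, Fos, Apold1 and Oasl2 in 5 each, Gadd45b in 4, Cyr61 in 3 and Timp1 in 2. Outside these 23, Galnt7 was also lost without a filter (edgeR adjusted p = 0.0564). With the block in a fit of only these groups Fos, Cyr61, Apold1, Gadd45b, Timp1, Oasl2, Fam167a and Galnt7 were not called. Without 4 of the 5 libraries, KO_tdT 4 being kept, 0 of the 18 calls remained, with an edgeR adjusted p of 0.135 for Gfap, Serpina3n and Vim and log2 changes of 1.37, 1.31 and 0.87. Of these groups that fit held only WT_hM4D 1 and 3 and WT_tdT 1, 2 and 3, so the lost calls cannot be told from the loss of replicates.

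In knockout mice the activated receptor was measured by KO_hM4D against KO_tdT. C4b rose from 19.76 ± 2.22 to 55.78 ± 17.3 CPM (SD, n = 4), a log2 change of 1.497 (SE 0.21, edgeR adjusted p = 0.0448), with 3 libraries between 63.29 and 66.49 CPM, replicate 2 at 29.93 CPM and all 4 above the 4 controls. Serpina3n, at 7.71 ± 0.866 and 14.32 ± 3.42 CPM, had a log2 change of 0.89 (SE 0.16, edgeR adjusted p = 0.134) and did not pass over all genes. Of the 26 reactive astrocyte genes 0 passed over all genes, 5 rose adjusted over the list alone (Serpina3n, Vim at 0.49, SE 0.09, Gfap at 0.71, SE 0.15, Timp1 and Cd109), and 22 had a positive change, with a median of 0.09 (camera adjusted p = 6.44e-06, adjusted p = 0.320 with an estimated correlation). The mean log2 level of this list was 1.58, 1.59 and 1.41 in KO_hM4D 1, 3 and 4, while KO_hM4D 2, at 1.17, lay within the 1.13 to 1.301 of KO_tdT. The values of smallest p after C4b and Serpina3n were those of the extracellular matrix gene Sned1 (-0.44, SE 0.07, edgeR adjusted p = 0.0879), the myomesin gene Myom3 (-0.51, SE 0.09, edgeR adjusted p = 0.134) and the chromatin remodeller Smarca1 (-0.30, SE 0.05, edgeR adjusted p = 0.134).

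Metabolic and tissue-state lists moved in this comparison. Cholesterol synthesis genes were lower in 20 of 25 cases and 4 passed adjusted over the list alone, such as Cyp51 (-0.31, SE 0.06) and Lss (-0.28, SE 0.08), with a median of -0.12 (camera adjusted p = 2.27e-06, adjusted p = 0.498 with an estimated correlation). All 13 mitochondrially encoded genes had a negative change with a median of -0.28 (camera adjusted p = 1.47e-06, adjusted p = 0.498 with an estimated correlation), and 0 passed adjusted over the list alone. The mean log2 level of this list was 6.80 and 6.71 in KO_hM4D 3 and 4, while KO_hM4D 1 and 2, at 7.31 and 7.23, lay within the 7.16 to 7.37 of KO_tdT. Glucocorticoid response genes were higher (15 of 18, median 0.17, camera adjusted p = 4.26e-05, adjusted p = 0.420 with an estimated correlation), with Tsc22d3 (0.39, SE 0.12) and Cables1 (0.30, SE 0.09) passing adjusted over the list alone. Interferon response genes (30 of 36 positive, median 0.15, camera adjusted p = 0.00483, adjusted p = 0.662 with an estimated correlation) and antigen presentation genes (20 of 23 positive, median 0.20, camera adjusted p = 0.00233, adjusted p = 0.654 with an estimated correlation) were higher, with 0 members passing adjusted over the list alone. Antigen presentation genes had mean log2 levels of 1.93 and 1.97 in KO_hM4D 3 and 4, and of 1.53 and 1.504 in KO_hM4D 1 and 2, within the 1.42 to 1.59 of KO_tdT. Immediate early genes did not differ detectably (median -0.08, camera adjusted p = 0.221), and Fos was 9.43 ± 2.26 CPM in KO_hM4D. Morphology and actin genes were slightly lower (median -0.03, camera adjusted p = 0.0242, adjusted p = 0.420 with an estimated correlation).

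Cell type markers moved too. Cortical excitatory neuron markers were higher (17 of 19, median 0.24, camera adjusted p = 0.00303, adjusted p = 0.662 with an estimated correlation), and oligodendrocyte markers (17 of 18 negative, median -0.28, camera adjusted p = 0.00154, adjusted p = 0.662 with an estimated correlation) and precursor markers (median -0.15, camera adjusted p = 0.0161, adjusted p = 0.567 with an estimated correlation) were lower. These shifts rest largely on KO_tdT 4, whose mean log2 level was 4.56 for cortical markers (5.24 to 5.63 in KO_tdT 1 to 3), 7.496 for oligodendrocyte markers (6.22 to 6.87) and 4.48 for precursor markers (4.06 to 4.30). Without KO_tdT 4 the medians were 0.10 for cortical markers and 0.00 for oligodendrocyte markers. Blood cell markers were lower in 7 of 7 cases (median -0.46, camera adjusted p = 0.000189, adjusted p = 0.420 with an estimated correlation). Interneuron markers were lower (median -0.19, camera adjusted p = 0.0486, adjusted p = 0.498 with an estimated correlation). Microglia markers (median 0.07, camera adjusted p = 0.0466, adjusted p = 0.739 with an estimated correlation), endothelial and mural markers (median 0.08, camera adjusted p = 0.0284, adjusted p = 0.505 with an estimated correlation) and clock genes (median 0.05, camera adjusted p = 0.00788, adjusted p = 0.498 with an estimated correlation) were higher. Igkc passed adjusted over the list of lymphocyte markers alone (7.34, SE 1.62), and so did the astrocyte genes Gja1 (-0.21, SE 0.06) and Aqp4 (-0.41, SE 0.12) in their list and the precursor gene C1ql1 (-0.53, SE 0.14) in its list. The other lists had camera adjusted p between 0.0543 and 0.910.

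Of 20825 genes 1 was called with edgeR in KO_hM4D against KO_tdT, 2313 had an unadjusted p under 0.05, and DESeq2 called 41 higher and 74 lower. The call of C4b was lost in 16 of the 23 alternatives with all groups in the fit, among them library totals, a term for sex and leaving out any of 12 single libraries, with log2 changes of 1.38 to 1.70. It was also lost with 1 CPM in 4 libraries, with limma-voom and with only these groups in the fit, with or without a block. All KO_hM4D libraries held Xist without Y-linked transcripts while KO_tdT 1 and 2 held the reverse, so sex and virus are partly confounded here.

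Whether hM4Di moved knockout expression back toward wild type was read from the genes called in KO_tdT against WT_tdT. Of the 7 without Dlgap3, 5 had the opposite sign in KO_hM4D against KO_tdT (71.4%), against 96.4% when unchanged groups shared the KO_tdT libraries and 64.3% with KO_tdT split 2 and 2. Btg2, at 8.41 ± 0.454 CPM in KO_tdT and 8.87 ± 1.54 CPM in KO_hM4D, and Dusp1, at 10.27 ± 1.80 and 10.36 ± 1.55 CPM, stayed below WT_tdT. Across 20825 genes, which are not independent replicates, the changes had r = -0.35 and a covariance of -0.0370. Unchanged groups gave r = -0.51 and a covariance of -0.0265, and the split libraries r = -0.06 (range -0.18 to 0.03) and a covariance of -0.0108. By sign and by correlation the observed reversal was no larger than unchanged groups gave. The shared KO_tdT libraries alone gave 96.4% opposite signs and r = -0.51, so neither measure could readily tell a reversal from them. The covariance differed from the simulated one by -0.0105, close to the -0.0108 of the split libraries. The SD of 0.0136 between the 6 splits, which overlap, is not the error of either value. These values therefore do not decide whether hM4Di moved expression back toward wild type.

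The knockout effect under hM4Di was measured by KO_hM4D against WT_hM4D. Dlgap3 fell by 1.296 (SE 0.10, n = 4 in each group, edgeR adjusted p = 6.66e-06). Its chromosome 4 neighbours Zbtb8a, a zinc finger gene (GRCm38 129353628 to 129378116), and Khdrbs1, an RNA-binding protein (GRCm38 129703164 to 129742303), fell as well. Zbtb8a changed by -0.73 (SE 0.11, edgeR adjusted p = 0.0492) from 8.94 ± 0.9995 to 5.40 ± 0.462 CPM, and Khdrbs1 by -0.52 (SE 0.08, edgeR adjusted p = 0.0484) from 101.1 ± 8.26 to 70.32 ± 7.45 CPM. Gm10093, a processed pseudogene on chromosome 17 (78491582 to 78493025), rose from 0.0849 ± 0.0473 to 1.297 ± 0.432 CPM, a log2 change of 3.91 (SE 0.53, edgeR adjusted p = 0.0170). The chemokine gene Cxcl10, next by p, had a change of -2.31 (SE 0.41, edgeR adjusted p = 0.112) and did not pass.

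Immune and glial lists were lower in KO_hM4D than in WT_hM4D. Of 36 interferon response genes 33 had a negative change and 6 passed adjusted over the list alone, led by Oasl2 (-0.98, SE 0.22) and Gbp2 (-0.61, SE 0.14), with a median of -0.35 (camera adjusted p = 9.23e-11, adjusted p = 0.420 with an estimated correlation). Of the 26 reactive astrocyte genes 3 were lower adjusted over the list alone, Cxcl10, Vim (-0.40, SE 0.09) and Gfap (-0.55, SE 0.15), with a median of -0.21 (camera adjusted p = 0.000885, adjusted p = 0.420 with an estimated correlation). Microglia markers (20 of 20 negative, median -0.11, camera adjusted p = 0.000153, adjusted p = 0.515 with an estimated correlation), antigen presentation genes (median -0.33, camera adjusted p = 0.000615, adjusted p = 0.567 with an estimated correlation) and blood cell markers (7 of 7 negative, median -0.50, camera adjusted p = 0.00191, adjusted p = 0.425 with an estimated correlation) were lower. Oligodendrocyte markers were lower in 18 of 18 cases (median -0.43, camera adjusted p = 1.37e-08, adjusted p = 0.498 with an estimated correlation). Precursor markers were lower in 11 of 12, with Pdgfra (-0.21, SE 0.07) and C1ql1 (-0.44, SE 0.14) among 4 passing adjusted over the list alone (median -0.25, camera adjusted p = 4.98e-05, adjusted p = 0.426 with an estimated correlation). Ependymal and choroid plexus markers were lower (17 of 18, median -0.42, camera adjusted p = 0.000540, adjusted p = 0.426 with an estimated correlation).

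Neuronal lists split in this comparison. Striatal projection neuron markers were lower (21 of 21, median -0.22, camera adjusted p = 0.000615, adjusted p = 0.662 with an estimated correlation) and cortical excitatory neuron markers higher (17 of 19, median 0.48, camera adjusted p = 6.09e-07, adjusted p = 0.498 with an estimated correlation). With a term for striatal minus cortical markers the projection neuron list turned higher (camera adjusted p = 0.00296). That term is computed from this list and the cortical list, so the changed direction is no independent result. Postsynaptic density genes (26 of 39 positive, median 0.06, camera adjusted p = 0.00564, adjusted p = 0.498 with an estimated correlation) and glucocorticoid response genes (15 of 18 positive, median 0.17, camera adjusted p = 0.000453, adjusted p = 0.498 with an estimated correlation) were higher. Immediate early genes did not differ detectably (median -0.05, camera adjusted p = 0.8294). The other lists had camera adjusted p between 0.0542 and 0.940, with the G protein gene Gnai2 (-0.22, SE 0.05), Fgfr3 (0.23, SE 0.07) and Gja1 (-0.21, SE 0.06) passing adjusted over their lists alone.

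Of 20825 genes 1 was higher and 3 lower with edgeR in KO_hM4D against WT_hM4D, 2636 had an unadjusted p under 0.05, and DESeq2 called 24 higher and 56 lower. With the replicate number as a block in a fit of these 8 libraries, 739 of 20127 genes were higher and 493 lower with 3 residual degrees of freedom, and 17 of 27 lists passed with the preset correlation and 0 with an estimated one. Beyond the lists that passed above, these were Gi signalling and cAMP genes (higher, median 0.02, camera adjusted p = 0.0318) and clock genes (higher, 0.0318). Direct pathway (0.00167), indirect pathway (0.00809) and mitochondrially encoded genes (0.0485) passed as lower. With an estimated correlation the Gi list had a camera adjusted p of 0.339. All 4 calls were kept in that fit. In the 23 alternatives with all groups in the fit Dlgap3 kept its call, while Zbtb8a and Khdrbs1 were lost in 13 each and Gm10093 in 7, and with only these groups and no block Khdrbs1 was not called (edgeR adjusted p = 0.168). The calls of the fit with the block included the Y-linked gene Ddx3y (-11.60, SE 0.21, edgeR adjusted p = 4.11e-07), since all KO_hM4D and no WT_hM4D libraries lack Y-linked transcripts. The count without single libraries was 1 without KO_hM4D 2, 3 or 4 or WT_hM4D 1, 3 or 4, 2 without KO_tdT 1 or 3 or WT_tdT 3 or 4, and 9 without WT_tdT 1.

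The interaction asked whether hM4Di acted differently by genotype. With edgeR 0 of 20825 genes passed, 1410 had an unadjusted p under 0.05, and DESeq2 called 6 higher and 7 lower. The smallest p belonged to early genes, whose hM4Di effect was more positive in knockouts. Dusp1 had a difference of 1.04 (SE 0.19), Btg2 of 1.25 (SE 0.23) and Csrnp1, outside the list of immediate early genes, of 0.68 (SE 0.13), each with an edgeR adjusted p of 0.407. The clock repressor Nr1d1 (0.82, SE 0.17) and the gene model Gm26783 (1.85, SE 0.38) followed with an edgeR adjusted p of 0.658 each. Dlgap3 (-0.07, SE 0.13, edgeR adjusted p = 0.934) and Chrm4 (-0.09, SE 0.21, edgeR adjusted p = 0.944) showed no detectable difference.

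As a list the 30 immediate early genes had 27 positive differences, 12 passing adjusted over the list alone and a median of 0.42 (camera adjusted p = 8.95e-18, adjusted p = 0.158 with an estimated correlation). WT_tdT was the group that stood apart, with Fos at 39.96 ± 11.2 CPM against 12.64 ± 2.45, 13.73 ± 4.79 and 9.43 ± 2.26 CPM in WT_hM4D, KO_tdT and KO_hM4D (SD, n = 4). Interferon response genes had 32 of 36 negative differences with a median of -0.33 (camera adjusted p = 1.17e-07, adjusted p = 0.498 with an estimated correlation), and reactive astrocyte genes 19 of 26 with a median of -0.22 (camera adjusted p = 0.000211, adjusted p = 0.420 with an estimated correlation), both with 0 members passing adjusted over the list alone. Of the heat shock genes Hspb1 (-0.98, SE 0.28) and Hspa5 (-0.61, SE 0.19) passed adjusted over the list alone (list median -0.21, camera adjusted p = 3.69e-05, adjusted p = 0.498 with an estimated correlation). Clock genes had 3 higher and 1 lower by that count, led by Nr1d1 and Cry1 (-0.51, SE 0.15). In all 14 lists passed with the preset correlation and 0 with an estimated one, and the other 13 had camera adjusted p between 0.0658 and 0.984. The count of genes was 4 without KO_tdT 4, 3 without WT_tdT 1 and 3 without the 5 libraries with both Xist and Y-linked transcripts.

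Averaged over both viruses, knockout against wild type gave 4 genes higher and 12 lower with edgeR, with 2919 at an unadjusted p under 0.05 and 86 higher and 124 lower with DESeq2. Dlgap3 fell by 1.26 (SE 0.07, edgeR adjusted p = 5.07e-08), Fos by 0.98 (SE 0.17, edgeR adjusted p = 0.0453), Btg2 by 0.72 (SE 0.11, edgeR adjusted p = 0.0232), Zbtb8a by 0.69 (SE 0.08, edgeR adjusted p = 0.00165) and Khdrbs1 by 0.47 (SE 0.06, edgeR adjusted p = 0.00188). Gm10093 rose by 3.12 (SE 0.35, edgeR adjusted p = 0.00149), Zbtb8os by 0.44 (SE 0.06, edgeR adjusted p = 0.0105) and the RNA-binding protein gene Trove2 by 0.17 (SE 0.03, edgeR adjusted p = 0.0267). Zbtb8a and Khdrbs1 were lower in 8 of 8 knockout libraries than in any wild-type library. The lists that passed here were those named in the separate genotype comparisons, such as projection neuron markers (21 of 21 negative, median -0.21, camera adjusted p = 4.26e-06, adjusted p = 0.567 with an estimated correlation) and oligodendrocyte markers (18 of 18 negative, median -0.28, camera adjusted p = 3.17e-07, adjusted p = 0.505 with an estimated correlation). The early genes had 2 members lower over all genes and 13 adjusted over the list alone (median -0.31, camera adjusted p = 9.92e-13, adjusted p = 0.316 with an estimated correlation). Fos and Btg2 were not called in KO_hM4D against WT_hM4D. The count was 163 without KO_tdT 4 and 772 without the 5 libraries with both Xist and Y-linked transcripts, where 15 of the 16 calls remained. It was 1, Dlgap3, when KO_tdT 4 was kept and the other 4 of those libraries were left out, so the 772 depends on KO_tdT 4. The fit with 772 calls held KO_tdT 1 and 2, WT_hM4D 1 and 3, WT_tdT 1, 2 and 3 and all of KO_hM4D. Fos was lost in 15 of the 23 alternatives with all groups in the fit, Trove2 in 14 and Btg2 in 10, while Dlgap3, Zbtb8a, Khdrbs1, Gm10093 and Zbtb8os kept their calls in them. Outside these 23, Fos was also lost with 1 CPM in 4 libraries (edgeR adjusted p = 0.0640) and Trove2 without a filter (edgeR adjusted p = 0.0896). Btg2 was lost with limma-voom (limma-voom adjusted p = 0.0679). The count was 7 without WT_tdT 4, 8 without KO_hM4D 2, KO_tdT 2 or WT_hM4D 3, 9 without KO_hM4D 1, KO_hM4D 4 or WT_hM4D 1, and 10 without KO_tdT 1.

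Genes called by genotype lay close to Dlgap3. In the averaged genotype comparison 8 of 571 genes within 20 Mb of Dlgap3 were called against 7 of 20253 elsewhere (odds ratio 41.0, two-sided Fisher's exact p = 1.65e-09), Dlgap3 itself left out. In KO_tdT against WT_tdT it was 2 against 5 (exact p = 0.0144), and in KO_hM4D against WT_hM4D 2 against 1 (exact p = 0.00221). The neighbours went both ways. Zbtb8a, Khdrbs1, Dcdc2b and CK137956 were lower, while Zbtb8os, whose annotated span overlaps that of Zbtb8a, and Spocd1 (1.57, SE 0.24, edgeR adjusted p = 0.0155) were higher. Counts of Zbtb8a and Zbtb8os are uncertain for that overlap, since the strand setting is not given. The transcript of Gm10093, on chromosome 17, is 99.4% identical over 1444 bases to Hdac1, a histone deacetylase gene on chromosome 4 (129516104 to 129542713), so reads of either may be counted to the other.

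**Figure D4:**
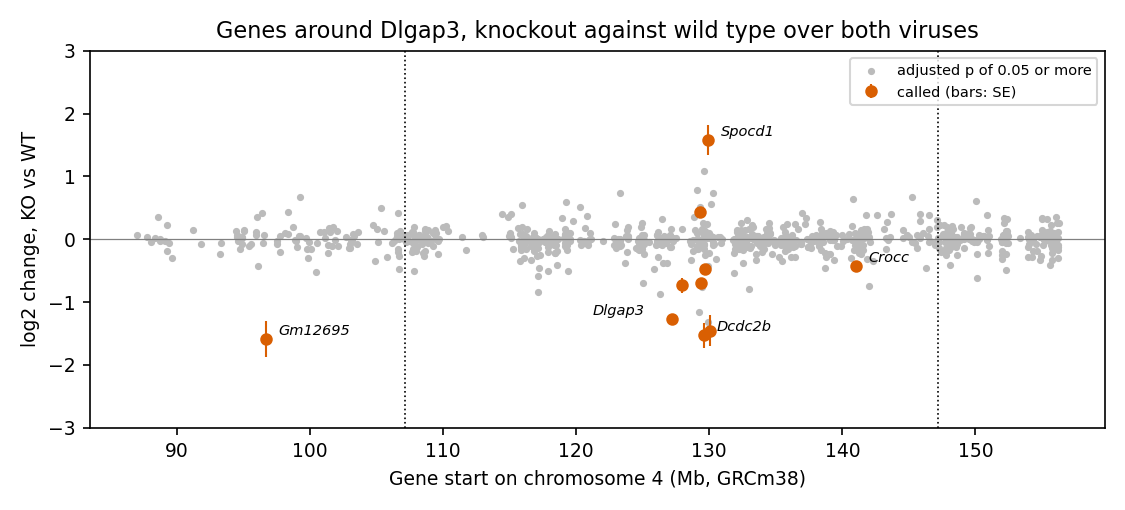
Log2 change of each tested gene around Dlgap3 in knockouts against wild types over both viruses (y axis), by the gene's start on chromosome 4 in Mb of GRCm38 (x axis). Orange points are genes called with edgeR, with bars of 1 SE, grey points the others, and dotted lines mark 20 Mb on either side of Dlgap3, a window that holds 8 called genes besides Dlgap3 itself.

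Averaged over both genotypes, hM4Di against tdTomato gave 5 genes higher and 1 lower with edgeR, with 3179 at an unadjusted p under 0.05 and 330 higher and 322 lower with DESeq2. C4b rose by 1.70 (SE 0.15, edgeR adjusted p = 7.96e-05), Serpina3n by 1.1997 (SE 0.11, edgeR adjusted p = 0.000103), Gfap by 1.02 (SE 0.11, edgeR adjusted p = 0.000324), Vim by 0.69 (SE 0.07, edgeR adjusted p = 0.000114) and Timp1 by 1.91 (SE 0.25, edgeR adjusted p = 0.00447). Fos fell by 1.10 (SE 0.17, edgeR adjusted p = 0.0317). All 8 hM4Di libraries lay above all 8 tdTomato libraries for C4b, Serpina3n and Vim. Of the 26 reactive astrocyte genes 4 rose over all genes and 11 adjusted over the list alone (median 0.24, camera adjusted p = 1.85e-19, adjusted p = 0.0206 with an estimated correlation). Interferon response genes had 16 of 36 higher adjusted over the list alone (median 0.31, camera adjusted p = 3.29e-16, adjusted p = 0.320 with an estimated correlation), and antigen presentation genes 17 of 23 (median 0.38, camera adjusted p = 6.12e-10, adjusted p = 0.420 with an estimated correlation), where replicates 3 and 4 of both hM4Di groups stood above the controls and replicates 1 and 2 did not. Of 25 cholesterol synthesis genes 7 were lower by that count, led by Cyp51 (-0.24, SE 0.05) and Mvd (-0.25, SE 0.06) (median -0.11, camera adjusted p = 2.05e-07, adjusted p = 0.498 with an estimated correlation). Direct pathway markers (camera adjusted p = 0.485) and indirect pathway markers (0.464) had 0 members passing adjusted over the list alone. The count was 0 without the 5 libraries with both Xist and Y-linked transcripts, 3 (C4b, Serpina3n and Vim) with KO_tdT 4 kept and the other 4 left out, 284 without KO_tdT 2, 62 without WT_hM4D 2, 59 without WT_hM4D 1, 15 without KO_hM4D 2 and 11 without WT_tdT 1. Across 20825 genes the hM4Di changes of both genotypes, which share no library, had r = 0.22 against -0.00 in unchanged groups, with a covariance of 0.0236, and C4b was higher in both. The simulated r varied by an SD of 0.0087, while deviations of real libraries from their group means correlated by -0.79 to 0.66 between groups. The simulation thus lacked differences that run across many genes, and the r cannot tell a shared response to hM4Di from these. Fos lost its call in 11 of the 23 alternatives and, outside these, with limma-voom (limma-voom adjusted p = 0.0548).

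Sex read from the transcripts was not balanced over the groups. All 4 KO_hM4D libraries and WT_tdT 1 held Xist, the RNA of the inactive X chromosome, with next to no Y-linked transcripts. In 6 libraries Y-linked transcripts prevailed, with Xist at 0 in KO_tdT 1 and 2 and at 0.620 to 1.96 CPM in WT_tdT 2 and 3 and WT_hM4D 1 and 3, at most 4.20% of the highest library. A further 5 libraries were counted as holding both, 4 of them at 5% or more of the highest library for each, and KO_tdT 4 with Y-linked transcripts at 4.93%, which is close to the 4.20% not counted. KO_tdT 3 had 26.4 CPM of Xist and 25.8 CPM of 4 Y-linked genes, KO_tdT 4 had 28.5 and 7.29 CPM, WT_hM4D 2 had 12.7 and 128 CPM, WT_hM4D 4 had 22.3 and 16.8 CPM and WT_tdT 4 had 27.1 and 20.5 CPM. Without these 5 libraries, 9 of the 30 immediate early genes were lower over all genes in KO_tdT against WT_tdT, and 3 in WT_hM4D against WT_tdT. Both counts were 0 when KO_tdT 4 was kept and the other 4 were left out, and 9 and 11 then passed adjusted over the list alone.

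**Figure D5:**
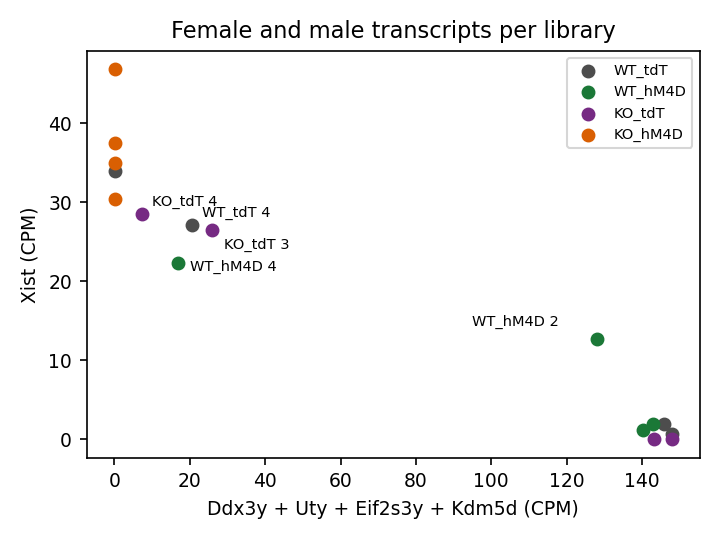
Xist (y axis, CPM) against the sum of the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d (x axis, CPM) for each of the 16 libraries, coloured by group. The 5 labelled libraries hold both kinds of transcript, for example KO_tdT 3 with 26.4 CPM of Xist and 25.8 CPM of Y-linked transcripts.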

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

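All tests of explanations in this part were chosen only after the results were seen. The exact test near Dlgap3 was a planned test, but it was set against an explanation only then. The search for single libraries far from their group and the interaction lists were planned.

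In 9 of 116 tests of 29 named genes in 4 groups, a library stood apart from the other 3 of its group, where chance gives about 5%. C4b was 29.9 CPM in KO_hM4D 2, below 63.3 to 66.5 CPM in the others. Junb was 70.7 CPM in KO_tdT 4, above 32.1 to 34.3 CPM. Btg2 was high at 10.8 CPM in WT_hM4D 1 and 11.2 CPM in KO_hM4D 3, and Cyr61 at 3.48 CPM in KO_hM4D 3. Fam167a was high at 1.26 CPM in WT_tdT 2 and Zbtb8a at 6.09 CPM in KO_hM4D 1, while Timp1 was low at 0.284 CPM in WT_hM4D 4 and Trove2 at 101.1 CPM in WT_hM4D 1.

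The effect of hM4Di differed between genotypes for 14 lists by the camera interaction test with the preset correlation, and for 0 with an estimated one. It was more positive in knockouts for immediate early genes (adjusted p = 8.95e-18), cortical excitatory neuron markers (1.17e-05), glucocorticoid response genes (1.20e-05), clock genes (0.00233) and postsynaptic density genes (0.00770). It was more negative for interferon response genes (1.17e-07), oligodendrocyte precursor markers (1.20e-05), heat shock genes (3.69e-05), thalamic, septal and pallidal markers (4.93e-05), reactive astrocyte genes (0.000211), blood cell markers (0.000386), oligodendrocyte markers (0.00280), microglia markers (0.00414) and antigen presentation genes (0.00951). Without KO_tdT 4 the median was -0.04 for oligodendrocyte markers and 0.26 for cortical markers, against -0.32 and 0.44 with it.

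Immediate early genes were highest in WT_tdT, and the list's median in the interaction was 0.42. Against sex of the mice, the median stayed at 0.40 with a term for the Y-linked share. Against a different mix of striatum and cortex, it was 0.47 with a term for striatal minus cortical markers. That term measures only this mix, so other differences in how tissue was taken stay open, untested. The time of collection may differ between groups and cannot be told apart from the groups. Sets of 10 and 5 genes from opposite arms of the clock differed by 0.20 in the interaction with an error of 0.221, too wide to decide. That error comes from the spread over the genes of each set and leaves out the spread between libraries. Per2 of the first set went against the difference. An effect of genotype and receptor on neuronal activity remains open beside the time of collection, untested.

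In KO_tdT 3 and 4, WT_hM4D 2 and 4 and WT_tdT 4 both Xist and Y-linked transcripts were at 4.93% or more of the highest library, and 4 libraries with Y-linked transcripts held Xist at 1.32 to 4.20%. A candidate explanation is that RNA of male and female mice met in 1 library. Shares of Xist (of 36.7 CPM) and of Y-linked transcripts (of 144.7 CPM) then add up to about 1, and the sums were 0.724 to 1.23, farthest from 1 at 0.724 in WT_hM4D 4. A wild-type male as the source in KO_tdT 3 is argued against, as Dlgap3 lay 7.30 SDs of the other knockout libraries below the level that its Y-linked share of 17.9% would bring. No biological explanation was tested.

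Genotype calls lay near Dlgap3, with an exact p of 1.65e-09 for 20 Mb. DNA of another strain carried along with the targeted allele may account for such neighbours, and an effect of the Dlgap3 loss on them stays open, untested. Reads of an altered Hdac1 allele counted to Gm10093 are a candidate source of its rise, with 99.4% identity, while Hdac1 itself was 9.99 ± 0.375 CPM in WT_tdT and 9.07 ± 0.427 CPM in KO_tdT. WT_tdT 2 lay at a median position of 0.41 between the wild-type (0) and knockout (1) levels over 10 genes near Dlgap3. The other wild types lay at -0.29 to 0.08, and WT_tdT 2 had the lowest wild-type Dlgap3. The 10 genes were those called in a fit without WT_tdT 2, so the other wild types lie near 0 partly by that choice. Single genes of WT_tdT 2 ranged from -0.39 to 0.84. Whether this mouse carries 1 knockout allele stays open. KO_hM4D 1, with Dlgap3 at the knockout level, lay at 0.70 against 0.98 to 1.17 in the other knockouts, so such departures also occur without an intermediate Dlgap3.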

How the results depend on the processing

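The terms for striatal minus cortical markers, the fits without the 5 libraries with both Xist and Y-linked transcripts and the block in fits of single pairs of groups were added after seeing the data. DESeq2 called more genes in each comparison, with 64 in KO_tdT against WT_tdT, 115 in KO_hM4D against KO_tdT, 240 in WT_hM4D against WT_tdT, 80 in KO_hM4D against WT_hM4D, 13 in the interaction, 210 by genotype and 652 by virus over both groups. With only the libraries of the groups compared the 4 pairwise counts were 1, 0, 49 and 7. The cause was not tested for any shift given here.

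The numbers 1 to 4 were tried as a replicate block. In all 16 libraries it gave 9, 0, 13 and 4 calls in the pairwise comparisons in that order, 0 in the interaction, 11 by genotype and 6 by virus. In fits of single pairs of groups the block gave 0, 4, 10 and 1232. Over all groups 9 of 24 same-numbered pairs had a correlation over 0.1 and 6 of 16 libraries matched their own number best, and the 4 pairs of KO_hM4D with WT_hM4D had 0.557, 0.486, 0.299 and 0.237. With the block in all 16 libraries 7 of 8, 0 of 1, 13 of 18 and 4 of 4 pairwise calls were kept, 9 of 16 by genotype and 5 of 6 by virus. The 83 lists that passed kept their call and direction. Named genes that lost theirs were C4b in knockouts, Oasl2 and Fam167a in wild types, Trove2 and Fos by genotype and Fos by virus.

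An adjusted p under 0.1 gave 2 calls in KO_hM4D against KO_tdT, 85 in WT_hM4D against WT_tdT, 28 by genotype and 375 by virus, and a 2-fold change left 2 in KO_hM4D against WT_hM4D and 6 by genotype. Library totals gave 0 in KO_hM4D against KO_tdT and 37 by virus, no filter gave 41 by virus, and 1 CPM in 4 libraries gave 0 in KO_hM4D against KO_tdT, 9 by genotype and 102 by virus. The limma-voom test gave 0 in KO_hM4D against KO_tdT. A term for sex gave 13 in KO_tdT against WT_tdT, 0 in KO_hM4D against KO_tdT, 28 in WT_hM4D against WT_tdT and 113 by virus. The term for striatal minus cortical markers gave 15, 2, 113 and 9 in the pairwise comparisons and 360 by virus. Without the 5 libraries there were 62, 0 and 1 in KO_tdT against WT_tdT, KO_hM4D against KO_tdT and KO_hM4D against WT_hM4D, 3 in the interaction, 772 by genotype and 0 by virus. KO_tdT 4 is in that set with Y-linked transcripts at 4.93% of the highest library, and with it kept and the other 4 left out, a fit also added after seeing the data, there were 1, 0, 1 and 1 in the pairwise comparisons, 1 in the interaction, 1 by genotype and 3 by virus. The count of 772 therefore depends on KO_tdT 4, and the genotype call that remained was Dlgap3. Without the 5 libraries KO_tdT 1 and 2, WT_hM4D 1 and 3, WT_tdT 1, 2 and 3 and all of KO_hM4D were left. A changed count in these fits cannot be told from an effect of fewer replicates.

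Leaving out each library gave 2 (KO_tdT 2, KO_tdT 3, WT_tdT 3) to 32 calls (KO_tdT 4) in KO_tdT against WT_tdT, with 3 without WT_tdT 4. It gave 0 to 8 in KO_hM4D against KO_tdT, 8 without KO_tdT 1 or WT_tdT 1, 4 without KO_hM4D 2, and 0 without KO_hM4D 1 or 3, KO_tdT 2, 3 or 4, any WT_hM4D, or WT_tdT 2 or 4. In WT_hM4D against WT_tdT it gave 6 (WT_tdT 4) to 65 (KO_tdT 2), with 8 without WT_tdT 3, 9 without WT_hM4D 3, 28 without KO_tdT 3, 38 without KO_tdT 4 and 42 without WT_hM4D 2. In KO_hM4D against WT_hM4D it gave 1 (KO_hM4D 2, 3 or 4, WT_hM4D 1, 3 or 4) to 9 (WT_tdT 1), with 2 without KO_tdT 1 or 3 or WT_tdT 3 or 4. The interaction had 0 to 4 (KO_tdT 4), with 3 without WT_tdT 1. By genotype it gave 7 (WT_tdT 4) to 163 (KO_tdT 4), with 8 without KO_hM4D 2, KO_tdT 2 or WT_hM4D 3, 9 without KO_hM4D 1 or 4 or WT_hM4D 1 and 10 without KO_tdT 1. By virus it gave 5 (KO_tdT 3) to 284 (KO_tdT 2), with 11 without WT_tdT 1, 15 without KO_hM4D 2, 59 without WT_hM4D 1 and 62 without WT_hM4D 2.

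Without single libraries Dlgap3 kept its call and direction, with log2 changes of -1.33 to -1.15 in KO_tdT against WT_tdT, -1.35 to -1.25 in KO_hM4D against WT_hM4D and -1.31 to -1.23 by genotype. It lost its call in KO_tdT against WT_tdT with the block in a fit of that pair (-1.22, edgeR adjusted p = 0.360). Where it was not called, it ranged from -0.03 to 0.02 by virus in knockouts, from -0.038 (WT_tdT 2) to 0.14 in wild types and from -0.15 to 0.03 in the interaction. Chrm4 ranged from -0.29 (KO_tdT 4) to 0.025 in KO_tdT against WT_tdT (-0.24 without the 5 libraries), from 0.38 to 0.71 (KO_tdT 4) in KO_hM4D against KO_tdT (0.34 with the term for sex, 0.70 without the 5 libraries) and from 0.52 to 0.64 in WT_hM4D against WT_tdT, where DESeq2 (0.59), the term for striatal minus cortical markers (0.58) and leaving out KO_tdT 4 brought it past the threshold. It ranged from -0.23 to -0.10 in KO_hM4D against WT_hM4D (-0.40 with the term for sex) and from -0.20 to 0.12 (KO_tdT 4) in the interaction (-0.32 with the term for sex, 0.12 without the 5 libraries). With KO_tdT split 2 and 2 the reversal had r = -0.0644 and a covariance of -0.0108.

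Of 189 list tests 83 passed, 4 with an estimated correlation and 4 with fry. With the term for striatal minus cortical markers 2 lists changed direction, projection neuron markers in KO_hM4D against WT_hM4D (adjusted p = 0.00296) and cortical markers by genotype (0.876). The term is computed from these same 2 lists, so their changed directions are no independent result. Of 1058 values of 46 gene results 861 kept direction and side, 15 gained a call, 1 moved, 0 changed direction and the others lost the call. Of 498 values of 83 list results 315 stayed, 2 changed direction and the others lost the call. At this depth the spread between libraries, rather than counting error, limits what can be called.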

Other observations

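The tests in this part of other splits of the libraries were planned, and the immunoglobulin levels and the list counts with fewer libraries were looked at only after the results had been seen. The exact tests of calls within 20 Mb of Dlgap3 were planned too, but their use here as an argument against chance was not.

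Plasma cell transcripts appeared in part of the hM4Di libraries. Igkc, an immunoglobulin light chain, was at most 0.112 CPM in all 8 tdTomato libraries. It was 0.634, 4.03, 2.85 and 14.7 CPM in WT_hM4D 1 to 4 and 0.101, 0.143, 17.6 and 19.9 CPM in KO_hM4D 1 to 4. The heavy chain Ighg2b reached 10.9 and 25.9 CPM in KO_hM4D 3 and 4 and 4.86 CPM in WT_hM4D 4, and Jchain, which joins secreted immunoglobulins, 6.28, 8.04 and 4.62 CPM in the same libraries. Ighm lay between 20.1 and 38.0 CPM in all groups, and these CPM are scaled with TMM factors over all genes. Igkc passed adjusted over the 14 lymphocyte markers alone in both hM4Di comparisons, but not over all genes.

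Thalamic transcripts stood out in single libraries. Shox2 was 0.0424 ± 0.0134 CPM in WT_tdT and 4.50 ± 6.44 CPM in KO_tdT (SD, n = 4), and the vesicular glutamate transporter Slc17a6 was 40.8 ± 21.1 CPM in KO_tdT. The mean log2 level of the thalamic, septal and pallidal list was 3.88 in KO_tdT 3, 3.05 in KO_tdT 4 and 3.71 in KO_hM4D 1, against 1.82 to 1.98 in WT_tdT. Without the 5 libraries with both Xist and Y-linked transcripts, 0 of the 20 markers passed adjusted over the list alone in KO_tdT against WT_tdT and the median was 0.28. In the same fit 4 of 15 heat shock genes rose over all genes and 10 adjusted over the list alone. With KO_tdT 4 kept and the other 4 left out, 1 thalamic marker passed adjusted over the list alone (median 0.53), and 0 heat shock genes rose over all genes and 8 adjusted over the list alone. Without KO_tdT 4, 13 of 30 immediate early genes fell over all genes in that comparison and 18 adjusted over the list alone, with a median of -0.65.

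Other splits of the same libraries were counted in fits of the groups compared. For WT_hM4D against WT_tdT the real split gave 49 genes and the others 1 at most, with 1 of 35 splits as large. For virus over both genotypes it was 6 genes against 2 at most, with 1 of 60 splits as large. These are the smallest shares that 35 and 60 splits can give, and they were not adjusted for the 7 comparisons. The counts therefore speak against chance in these 2 comparisons without excluding it. By the number of calls alone chance cannot be excluded for KO_tdT against WT_tdT (1 gene, highest other 1867, 3 of 35 splits as large), for KO_hM4D against WT_hM4D (7 genes, highest other 1152, 3 of 35) or for genotype over both viruses (16 genes, highest other 29, 3 of 60). The splits of KO_hM4D and WT_hM4D with 1152 and 445 genes part 2 and 0 of the 4 same-numbered pairs, and among the 8 splits that part all 4 pairs the real one had 7 genes and the others 0, which are too few splits for a share under 0.05. That comparison was made after the counts had been seen. For KO_hM4D against KO_tdT (0 genes, highest other 7) and the interaction (0 genes, highest other 71) the real split called no gene, so all 35 and all 60 splits are as large by construction and the count says nothing about chance. The identity of the genotype calls argues against chance for part of them. Dlgap3 was lower in all 8 knockout libraries than in any wild-type library, and 8 of the other 15 calls over both viruses lay within 20 Mb of it (exact p = 1.65e-09). The splits with 1867, 1152 and 445 genes point to a structure of the samples. The split with 445 genes set replicates 1 and 2 of KO_hM4D and WT_hM4D against replicates 3 and 4. The split with 1867 genes set KO_tdT 1, 2 and 3 and WT_tdT 3 against the other 4, and these 4 libraries had striatal minus cortical marker levels of 2.55, 2.98, 3.03 and 2.56 on the log2 scale against 3.39 to 4.38 in the others.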
